A study of Homo sapiens with 34 samples.

How the data were processed

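Expression was measured on 34 Affymetrix 3' expression arrays hybridised with biotin-labelled cRNA from cultured immortalized human astrocytes. The deposited values are log2, made by the authors with RMA, which corrects background, normalises by quantiles and summarises each probe set. No version of RMA, no genome build and no statement of which arrays were normalised together are given in the sources used here. The log2 scale was checked on the values. No counts or depths apply to arrays, so their number limits the precision.

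Groups came from the labels alone. The 30 time-course arrays form 6 groups (parental or mutant line without doxycycline, with it, or withdrawn from it), with 1 array per group at each of 5 passages. The 4 sorted arrays form 2 groups of 2. The labels name no separate cultures, so passages were taken as the repeats. In the main fit, p-values refer to how groups varied from passage to passage after the passage term, not to a spread between separate cultures.

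Of 22277 probe sets, 19070 carried exactly 1 gene symbol, 1043 several, and 2164 had no name in the annotation used here. Symbols were brought to their present form through gene identifiers. For each of 11963 genes the probe set with the highest mean over all arrays was kept. Genes above 4.83 log2, the 40th percentile of all values, on at least 5 of 30 arrays were tested (8381), or on at least 2 of the 4 sorted arrays (8168). Where 1 of 2 compared groups has a mean under this value, the log2 change is taken as a lower bound, and for differences of effects the direction of the bound was worked out from the sign of each group. Probe sets without exactly 1 symbol were left out of the comparisons and are reported in the closing section.

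Models were fitted with limma 3.58.1 in R 4.3.3. The time-course model had a term for each of the 6 groups and a term for each passage, with 20 residual degrees of freedom, and contrasts of groups gave each comparison. The passage term rests on the passage stated in the labels. Of 75 pairs of arrays from the same passage, 67 had a correlation of residuals above 0.1, with a median of 0.341 and a lowest of -0.216, against a median of -0.0529 for other pairs. The pairing was thus not visible in every pair, and results without the passage term are given for the time-course comparisons and the trends in mutant cells. Trends were tested in a model with slopes on log2 of the passage number (15 residual degrees of freedom), and the sorted populations in a model of the 4 arrays (2 residual degrees of freedom). Genes with a Benjamini-Hochberg adjusted p under 0.05 in a comparison are called.

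Gene lists were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives, and no list called by camera held with an estimated correlation in any comparison, while the 2 sets of CD24 sort genes held for the doxycycline effect in mutant cells and for the lines without doxycycline. The 23 lists cover neural progenitor, astrocyte, neuron, oligodendrocyte lineage, leukocyte, endothelial, mesenchymal and matrix, and epithelial markers. They also cover cell cycle, interferon, class I, NF-kB, hypoxia and glycolysis, TCA cycle and glutamate, ATF4, cholesterol, oxidative phosphorylation, chromatin enzymes, G-CIMP glioma markers, HOX, germline, p53 and histone genes. The endothelial and germline lists had fewer than 3 tested members in the time course and were not tested, which leaves 21.

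Named genes are IDH1, CD24 and L1CAM in every comparison, and up to 10 called genes per direction with the largest change among those with 1 sign at all 5 passages, or, for the sort, with both positive arrays on 1 side of both negative arrays. For lists, up to 4 members with the smallest p are named. The groups, comparisons, lists, naming rule and alternatives were fixed before the data were examined.

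The retained share was computed per passage. Genes were called between treated and never-induced mutant arrays without that passage. The difference of withdrawn or treated from never-induced cells at the passage was then regressed through 0 on the mean doxycycline effect of the other passages, and the ratio of the withdrawn to the treated slope is the retained share. The CD24 sort genes were tested in the time course with camera as 2 sets, and sort changes were correlated with each comparison across genes.

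The alternatives were no passage term, passage as a random block, only the groups compared, array weights, no filter or the 60th percentile, the mean of all probe sets of a gene, quantile normalization, median centring, a trended robust prior, and leaving out each passage or sorted array. For the sort, a replicate block and a fit of all 34 arrays were added, and for the retained share other baselines, gene choices and a median of ratios.

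The gene comparisons were tested on simulated data with 200 changed genes. A log2 change of 1 was recovered for 96% of genes in the mutant doxycycline effect, 89.5% in the difference between lines and 75% in the sort, and a change of 0.5 for 63.5%, 33.5% and 0%. A trend of 0.25 per doubling was recovered for 66%. False calls numbered 0 to 16 per simulation. In a separate simulation a retained share set to 40% at every passage was returned as 38.4% to 40.6%. It had more changed genes, changes mostly larger than those of the called genes, and independent noise, so it does not give the precision of the shares reported below.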

Results

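Gene expression was measured in immortalized human astrocytes, glial cells made to divide without limit in culture, on 34 Affymetrix arrays. The mutant line carried IDH1 R132H under a doxycycline-inducible promoter. This changed form of isocitrate dehydrogenase makes 2-hydroxyglutarate, a compound that inhibits enzymes which remove methyl groups from DNA and histones. The parental line carried the empty vector. Each line was kept without doxycycline, with doxycycline at 1 µg/ml, or taken off doxycycline, which gave 6 groups of 5 arrays, 1 array per group at title numbers 1, 5, 10, 20 and 40. The title number counts passages from a baseline at passage 30, and it is called the passage below. At title number 1, the never-treated and treated arrays were taken at the baseline and the withdrawn arrays 1 passage after it. The other 4 arrays came from doxycycline-treated mutant cells, 20 passages after the baseline, sorted into 2 CD24-positive and 2 CD24-negative samples. CD24 is a small glycosylated protein of the cell surface. Passage 40 was hybridised in another array run than passages 1 to 20, and the sorted arrays in a further one. The 3' minus 5' log2 difference of ACTB control probe sets, a sign of RNA quality, averaged 1.01 at passages 1 to 20, 0.594 at passage 40 and 1.75 in sorted arrays. The median log2 value per array ran from 5.74 to 5.93, and the number of arrays limits the precision of each comparison. The labels give 1 array per group and passage and name no separate cultures, so passages were taken as the repeats. As labelled, each genotype is 1 line, and other differences between the lines cannot be separated from it. Each group may likewise be 1 culture sampled at 5 passages. A treatment effect named below then cannot be separated from a drift of that culture. Where a mean of 1 of 2 compared groups lies under 4.83 log2, the filter value, the log2 change is taken as a lower bound, and no fold is given. In a difference of effects such a mean can work either way.

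In mutant cells, doxycycline raised CAPN6 and CXADR and lowered COL3A1 and MEOX2. CAPN6, a calpain family member without protease activity, rose from 2.76 ± 0.10, under the filter value of 4.83, to 7.01 ± 1.67 log2 (SD, n = 5 in each group). CXADR, the coxsackievirus and adenovirus receptor of cell junctions, rose 9.04-fold, from 4.95 ± 0.48 to 8.13 ± 0.29. COL3A1, the chain of type III collagen, was 9.62-fold lower, from 10.97 ± 1.17 to 7.71 ± 2.15, and MEOX2, a homeobox transcription factor of mesenchyme, fell from 6.74 ± 0.18 to 3.53 ± 0.76, also under that value. The comparison asks what induction of the mutant enzyme changed. With limma, 2322 of 8381 tested genes differed, 1006 higher and 1316 lower, of which 162 and 103 changed at least 2-fold.

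The other genes with the largest rises were COLEC12, a scavenger receptor (log2 change 3.03), AKR1C3, an aldo-keto reductase of steroid metabolism (2.98), ADGRG6, an adhesion receptor (2.82), and ACTC1, cardiac actin (2.76). They also included GBP2, an interferon-inducible guanylate-binding protein (2.73), HS3ST3A1, a heparan sulfate sulfotransferase (2.62), ACKR3, an atypical chemokine receptor (2.53), and SKAP2, a signalling adaptor (2.53, with 3 of its 4 probe sets higher). The largest falls included VCAM1, an adhesion molecule for leukocytes (-2.71), KIT, the receptor of stem cell factor (-2.41), KCNJ8, a potassium channel subunit (-2.36), and THBS2, a thrombospondin of the matrix (-2.36). ADGRL3, a latrophilin, changed by -2.22, ADAMTS5, a protease of proteoglycans, by -2.16, NLGN1, a synaptic adhesion protein, by -2.16, and CDH6, a cadherin, by -2.08. Means under the filter value, so lower bounds, hold for CAPN6, COLEC12, AKR1C3, ADGRG6, HS3ST3A1, SKAP2, MEOX2, KIT, KCNJ8, ADGRL3 and NLGN1. Standard errors of the 20 changes ran from 0.22 to 0.64, each had 1 sign at 5 of 5 passages, and adjusted p ran from 4.26e-07 to 0.00117. CD24 rose by 1.67 (SE 0.36, adjusted p = 0.00132, higher at 5 of 5 passages and on 6 of 6 probe sets). L1CAM, a neural cell adhesion molecule, rose by 2.17 (SE 0.39, adjusted p = 0.000257), with 4 of 5 passages higher. At passage 40 it stood at 5.10 in treated and 5.59 in never-induced cells, and its second probe set gave a change of 0.37. IDH1 itself had a log2 change of -0.15 (SE 0.11, adjusted p = 0.312) on 1 probe set. Where that probe set lies relative to the introduced sequence is not given in the sources used here, so this value is no measure of induction.

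Interferon-response genes rose in mutant cells under doxycycline, 11 of 21 tested and 12 adjusted over the list alone, and none fell (camera adjusted p = 3.89e-05, adjusted p = 0.308 with an estimated correlation). IFI44 rose by 1.77, IFIT1 by 1.65, the RNA sensor RIGI by 1.02 and USP18, which removes ISG15 from proteins, by 0.87. Of 14 class I antigen-presentation genes 10 rose and 1 fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.000424, adjusted p = 0.351 with an estimated correlation). PSMB9, a subunit of the immunoproteasome, rose by 0.89, the peptidase ERAP1 by 0.45, TAPBP by 0.43 and B2M, the light chain of class I molecules, by 0.31. Histone genes rose in 6 of 9, also adjusted over the list alone (camera adjusted p = 3.89e-05, adjusted p = 0.226 with an estimated correlation), among them H2AC6 by 1.22, H2BC12 by 1.21, H2BC5 by 0.93 and H1-2 by 0.93. Of 8 epithelial genes 3 rose, also adjusted over the list alone, MUC1 by 1.82, KRT7 by 1.29 and KRT18 by 1.26 (camera adjusted p = 0.0279, adjusted p = 0.226 with an estimated correlation and 0.189 with no filter). RNA quality differed as well. The ACTB 3' minus 5' difference was higher in treated than in never-induced mutant arrays at 5 of 5 passages, by 0.139 on average (SD 0.0484), and so was that of GAPDH, by 0.0630 (SD 0.0419). In parental cells the means were -0.00650 (SD 0.171) and 0.0386 (SD 0.0463).

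Other lists moved in both directions or did not pass camera in the mutant line. Of 28 mesenchymal and matrix genes 4 rose and 11 fell, 5 and 12 adjusted over the list alone (camera adjusted p = 0.0917, but 0.0354 with no filter and 0.00452 with fry), with PDGFRB at -1.25, SNAI2 at -0.94, TWIST1 at -0.92 and COL4A1 at -0.88. Among 17 NF-kB genes 3 rose and 5 fell, the same numbers adjusted over the list alone (adjusted p = 0.229), including the chemokine CXCL8 at -1.93, LIF at -1.01 and TNFAIP3 at -0.66. Among 24 hypoxia and glycolysis genes 7 rose and 2 fell, 8 and 2 adjusted over the list alone (adjusted p = 0.167), including NDRG1 at 1.78, the angiogenic factor VEGFA at 1.39 and the glucose transporter SLC2A3 at 1.29, while the glycolytic enzyme TPI1 fell by 0.36. Of 15 neural progenitor genes, a list that holds CD24 and L1CAM, 4 rose and 2 fell, 5 and 6 adjusted over the list alone, among them SOX9 at 1.37, and the list's median of -0.15 and mean of 0.20 differed in sign (adjusted p = 0.889). The astrocyte list had 2 of 9 higher, also adjusted over the list alone, CLU at 1.06 and NDRG2 at 0.48 (adjusted p = 0.0938). The neuron list had 3 of 10 higher, 4 adjusted over the list alone, UCHL1 at 0.53, MAP2 at 0.54 and GAD1 at 0.56 (adjusted p = 0.155). Of 23 chromatin enzymes 3 rose and 4 fell, also adjusted over the list alone, with the DNA methyltransferases DNMT3A at -0.64 and DNMT3B at -0.44, KDM2A at 0.35 and EZH1 at -0.53 (adjusted p = 0.996, median 0.04 and mean -0.06).

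Lists with few called members in that comparison follow. Of 5 oligodendrocyte-lineage genes PDGFRA rose by 1.32 and MBP, the myelin basic protein, fell by 1.27 (adjusted p = 0.996, median -0.02 and mean 0.06). None of 3 leukocyte genes was called by limma, and AIF1 had the smallest p of them with a change of 0.31 (adjusted p = 0.787). None of 5 HOX genes was called, HOXB5 standing at -0.18 (adjusted p = 0.996). Of 30 cell cycle genes 3 rose and 4 fell, CCNB2 at 0.40 and TYMS at -0.23 (adjusted p = 0.787). Of 26 TCA cycle and glutamate genes 5 rose and 1 fell, ME1 at 0.46 and IDH3G at -0.24 (adjusted p = 0.336). Of 27 ATF4 and amino-acid genes 2 rose and 3 fell, 2 and 1 adjusted over the list alone, with VLDLR at 0.85 and STC2 at -0.52 (adjusted p = 0.793). Of 17 cholesterol biosynthesis genes 3 fell, FDPS at -0.40 and LSS at -0.37 (adjusted p = 0.167). Of 29 oxidative phosphorylation genes 2 rose and 3 fell, COX5A at 0.32 and NDUFB8 at -0.26 (adjusted p = 0.438). Of 6 G-CIMP glioma marker genes 1 rose, LGALS3 at 0.66, and 2 adjusted over the list alone (adjusted p = 0.168). Of 15 p53 targets 1 rose and 2 fell, BAX at -0.34 and DDB2 at -0.50 (adjusted p = 0.889). Without the passage term 1187 genes were called, 564 higher and 623 lower, and leaving out passage 10 or passage 20 gave 1429 or 1426, while CD24, L1CAM and the 20 genes with the largest changes stayed called with any 1 passage left out.

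**Figure D1:**
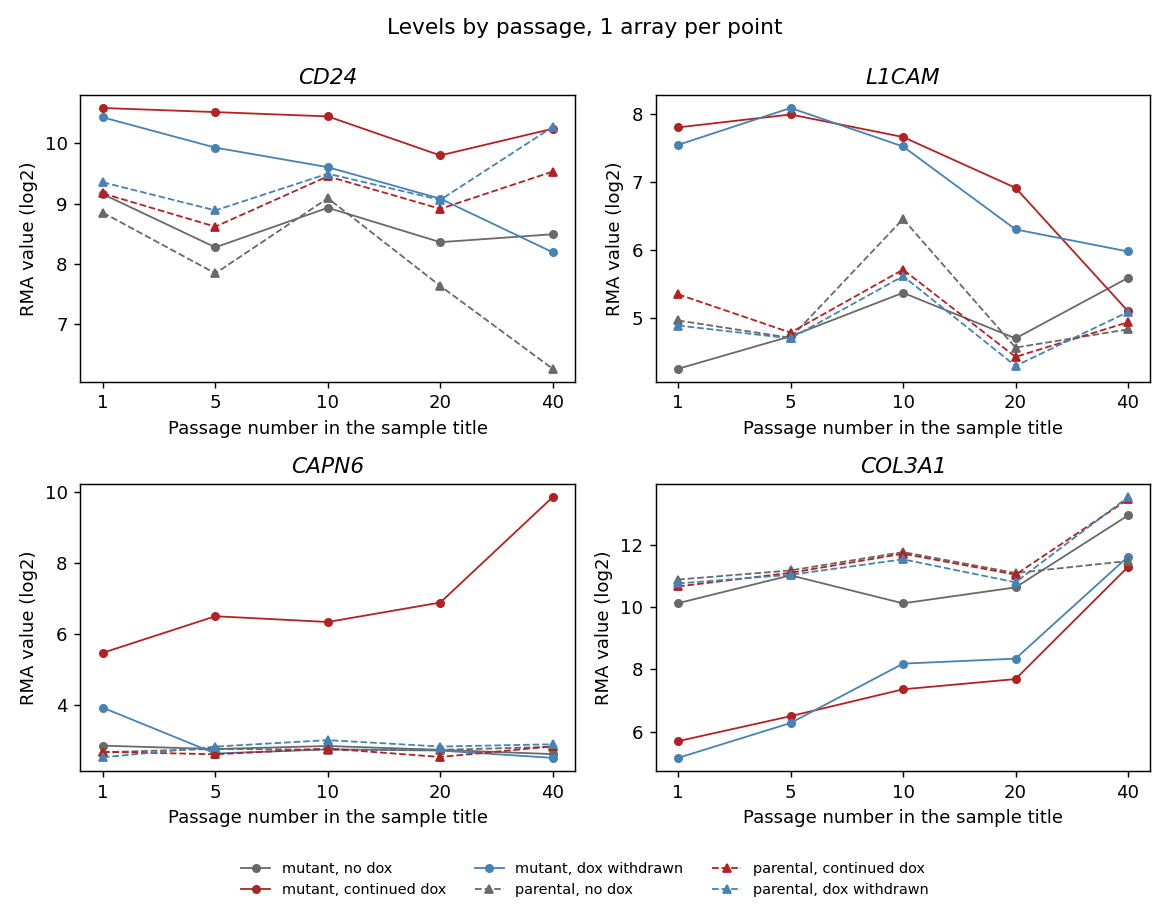
Log2 RMA values (vertical axes) of 4 genes in each of the 6 groups against the passage number in the sample title (horizontal axes), 1 array per point. CAPN6 at passage 40 stood at 9.86 in treated mutant cells and 2.51 in withdrawn mutant cells, and L1CAM at passage 1 at 7.81 and 7.55.

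In parental cells, doxycycline gave 1 called gene, MSRA, a methionine sulfoxide reductase, which rose from 7.89 ± 0.11 to 8.37 ± 0.13 log2 (SD, n = 5; change 0.48, SE 0.08, adjusted p = 0.0176, higher at 5 of 5 passages). CD24 had a change of 1.20 (SE 0.36, adjusted p = 0.528) and was higher at 5 of 5 passages without passing the test, with a change of 0.68 without passage 40, where its never-treated array stood at 6.27 against 7.64 to 9.09 before. L1CAM had a change of -0.06 (SE 0.39) and IDH1 one of 0.04 (SE 0.11). The comparison is the control for doxycycline itself. With limma, 526 genes had an unadjusted p under 0.05. By camera the cholesterol biosynthesis list was lower (adjusted p = 2.78e-11, adjusted p = 0.307 with an estimated correlation), with 0 of 17 genes called by limma and 3 lower adjusted over the list alone, and INSIG1 at -0.45. The NF-kB list was lower (adjusted p = 0.000298, adjusted p = 0.307 with an estimated correlation), with 0 of 17 called by limma and 1 lower adjusted over the list alone, and CXCL8 at -1.26. The class I list was higher (adjusted p = 0.000298, adjusted p = 0.578 with an estimated correlation), with 0 of 14 called by limma or adjusted over the list alone, and HLA-C at 0.43. MSRA was not called without the passage term or without any of passages 1, 5, 10 or 20 (0 genes each), and 7 genes were called without passage 40 and 24 with array weights.

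Tested directly, the doxycycline effect differed between the lines for COLEC12, CAPN6, DEPTOR, MEOX2 and COL3A1, among others. COLEC12 had the largest positive estimate among the named genes, 4.59 (SE 0.90), with means of 4.40 ± 1.70 and 7.43 ± 1.71 log2 in never-induced and treated mutant cells and 6.23 ± 0.36 and 4.67 ± 0.54 in parental cells (SD, n = 5). Its rank over CAPN6 is not settled, as both had means under the filter value. DEPTOR, an inhibitor of mTOR, differed by 3.35 (SE 0.35), with 4.32 ± 0.68 and 6.80 ± 0.82 in mutant and 5.64 ± 0.62 and 4.78 ± 0.43 in parental cells. MEOX2 differed by -3.79 (SE 0.65) and COL3A1 by -3.58 (SE 0.76). With limma, 795 genes differed, 366 with a more positive and 429 with a more negative effect in mutant cells. Of the 2322 genes called in mutant cells, 752 were also called here in the same direction, from overlapping arrays.

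Positive differences were found for CAPN6 (4.31), AKR1C3 (3.11), ADGRG6 (3.07), SERPINB3, a protease inhibitor (2.95), ACTC1 (2.56), LIMCH1 (2.50), HS3ST3A1 (2.36) and CXADR (2.33). Negative differences were found for KCNJ8 (-3.06), NLGN1 (-2.78), THBS2 (-2.38), the small GTPase RAB38 (-2.32), VCAM1 (-2.29), LGR5, a receptor for R-spondins (-2.22), KCNE4, a potassium channel subunit (-2.21), and RCAN2, a calcineurin regulator (-2.20). Of the 21 called named genes 14 had a group mean under the filter value. For COLEC12, DEPTOR, MEOX2, NLGN1, RAB38, KCNE4 and RCAN2 this makes the difference a lower bound, for CXADR, with its low mean of 4.67 in never-treated parental cells, an upper bound, and for CAPN6, AKR1C3, ADGRG6, SERPINB3, HS3ST3A1 and KCNJ8 it can work either way. Standard errors of the 20 differences ran from 0.34 to 0.90, and each had 1 sign at 5 of 5 passages. L1CAM differed by 2.24 (SE 0.55, adjusted p = 0.0122, 4 of 5 passages), but by 0.37 on its second probe set. CD24 had a difference of 0.47 (SE 0.50, adjusted p = 0.602), and 0.97 without passage 40 (adjusted p = 0.0323). IDH1 had a difference of -0.20 (SE 0.15, adjusted p = 0.451). Histone genes differed in 4 of 9, 6 adjusted over the list alone (camera adjusted p = 0.000268, adjusted p = 0.206 with an estimated correlation), with H2AC6 at 1.08. Interferon genes differed in 3 of 21, 5 adjusted over the list alone (camera adjusted p = 0.000268, adjusted p = 0.562 with an estimated correlation), with IFIT1 at 1.66 and IFI44 at 1.51. Epithelial genes differed in 3 of 8, 4 adjusted over the list alone (camera adjusted p = 0.0176, adjusted p = 0.206 with an estimated correlation and 0.225 with no filter), with MUC1 at 1.77. Hypoxia genes differed in 3 of 24, all more positive, with NDRG1 at 1.98, and in 6 and 2 adjusted over the list alone (camera adjusted p = 0.0254, adjusted p = 0.562 with an estimated correlation). The class I list, which camera called higher with doxycycline in both lines, was not called for the difference (camera adjusted p = 0.117, adjusted p = 0.828 with an estimated correlation). Without the passage term 220 genes were called, and without passage 1, 5, 10 or 20 the counts were 419, 357, 324 and 265, while array weights gave 1484 and leaving out passage 40 gave 1140. L1CAM, RAB38, LGR5, VCAM1, KCNE4 and RCAN2 each lost the call without at least 1 of these passages, and L1CAM, HS3ST3A1, COL3A1, RAB38, VCAM1, LGR5 and RCAN2 without the passage term.

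After withdrawal, several genes that doxycycline had raised in mutant cells were lower again than in cells kept on it. CAPN6 fell by 4.10 (SE 0.44), to 2.91 ± 0.58 log2 (SD, n = 5) against 2.76 ± 0.10 in never-induced cells. Also lower were COLEC12 (-2.67), GBP2 (-2.06), ACTC1 (-2.04), S100A4, a calcium-binding protein (-1.97), ADGRG6 (-1.93), AKR1C3 (-1.91), FBXO2 (-1.87), the potassium channel KCNK15 (-1.81) and CXADR (-1.74). ADAMTS5 rose by 1.49, KIT by 1.38, KISS1, the kisspeptin precursor, by 1.18, THBS2 by 1.10, ARSJ by 1.06, INHBA, an activin subunit, by 1.05, KCTD12 by 1.02, PTN, the growth factor pleiotrophin, by 0.99, OPN3 by 0.99 and the pseudogene PDCD6IPP2 by 0.92. The study follows how expression reverses once the mutant enzyme is lost. This comparison asks what withdrawal reversed, on average over the 5 passages. With limma, 217 genes differed, 94 higher and 123 lower. Means under the filter value hold for CAPN6, COLEC12, AKR1C3, FBXO2, KCNK15 and KIT. Standard errors of the 20 named changes ran from 0.15 to 0.64, adjusted p from 2.17e-05 to 0.0498, and each had 1 sign at 5 of 5 passages. CD24 had a change of -0.87 (SE 0.36, adjusted p = 0.183, lower at 5 of 5 passages; -0.58 without passage 40), L1CAM one of -0.01 (SE 0.39, adjusted p = 0.994) and IDH1 one of 0.12 (SE 0.11, adjusted p = 0.571).

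Interferon genes fell in 3 of 21, IFI44 (-1.14), IFI6 (-0.89) and USP18 (-0.77), and in 11 adjusted over the list alone, between withdrawn and treated mutant cells (camera adjusted p = 5.38e-07, adjusted p = 0.423 with an estimated correlation). Histone genes fell in 3 of 9, H2AC6 (-0.68), H2BC5 (-0.67) and H1-2 (-0.66), and in 6 adjusted over the list alone (camera adjusted p = 0.00026, adjusted p = 0.423 with an estimated correlation). The class I list was lower with 0 of 14 called by limma or adjusted over the list alone, ERAP1 at -0.37 (camera adjusted p = 0.00893, adjusted p = 0.711 with an estimated correlation). The cholesterol list was higher with 0 of 17 called by limma or adjusted over the list alone, SQLE at 0.35 (camera adjusted p = 0.0231, adjusted p = 0.755 with an estimated correlation and 0.0621 without the passage term). A fit of these 10 arrays alone called 0 genes, the fit without the passage term 36, the fit without the filter 115, the fit with array weights 100, and the counts without passage 5, 10 or 20 were 52, 22 and 7. ADAMTS5, CAPN6 and ACTC1 stayed called with any 1 passage left out, PTN and AKR1C3 lost the call only without passage 20, and the other 15 without at least 1 of passages 5, 10, 20 or 40. Without passage 40 the changes were -1.68 for COLEC12, -1.11 for GBP2, -1.21 for S100A4, -1.29 for ADGRG6, -1.12 for FBXO2, 0.91 for KIT, 0.72 for THBS2, 0.68 for KCTD12 and 0.64 for OPN3, each over 1.5 times smaller.

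Compared with never-induced cells, withdrawn mutant cells had lower COL3A1 and DOCK2 and higher L1CAM. COL3A1 was lower by 3.06 (log2 change -3.06, SE 0.53, 3 of 4 probe sets), at 7.92 ± 2.47 log2 against 10.97 ± 1.17 (SD, n = 5). L1CAM rose by 2.17 (SE 0.39, adjusted p = 0.00288, 5 of 5 passages), at 7.09 ± 0.90 against 4.93 ± 0.55, but by 0.46 on its second probe set. DOCK2, an activator of the GTPase Rac, fell by 2.18 (SE 0.22), to 3.53 ± 0.28 from 5.71 ± 0.56, and FAM50B, an imprinted gene, fell by 1.36 (SE 0.14). This comparison asks what persisted on average over the 5 passages, the first of them 1 passage after withdrawal. A called gene need not still differ at the last passages: TNFRSF21, named below, differed by 0.20 at passage 40, against 1.32 to 1.48 before. With limma, 342 genes differed, 119 higher and 223 lower.

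Also higher in withdrawn cells were BEX1 (1.97), DEPTOR (1.49), TMEM158 (1.47), CXADR (1.44), PODXL, a sialomucin (1.39), ANKRD1 (1.32), ACKR3 (1.23), LIMCH1 (1.21) and the death receptor TNFRSF21 (1.18). Lower were VCAM1 (-1.80), MEOX2 (-1.79), the adaptor EFS (-1.41), THBS2 (-1.26), PAPPA, a protease of insulin-like growth factor binding proteins (-1.23), PLTP, the phospholipid transfer protein (-1.18), and GALC, the lysosomal galactosylceramidase (-1.12). Means under the filter value hold for BEX1, DEPTOR, DOCK2, EFS, FAM50B and GALC. Standard errors of the 20 named changes ran from 0.14 to 0.53, and each had 1 sign at 5 of 5 passages. CD24 had a change of 0.80 (SE 0.36, adjusted p = 0.213, higher at 4 of 5 passages), and 1.08 without passage 40 (adjusted p = 0.00131). IDH1 had a change of -0.03 (SE 0.11, adjusted p = 0.907). Histone genes rose in 1 of 9, H2BC12 by 0.61, and 3 adjusted over the list alone (camera adjusted p = 0.0101, adjusted p = 0.355 with an estimated correlation). Neuron genes rose in 2 of 10, MAP2 by 0.57 and UCHL1 by 0.39, and 4 adjusted over the list alone (camera adjusted p = 0.0148, adjusted p = 0.0734 with an estimated correlation). The class I list was higher with 0 of 14 called by limma or adjusted over the list alone, PSMB9 at 0.49 (camera adjusted p = 0.0148, adjusted p = 0.541 with an estimated correlation and 0.0504 without the passage term). The epithelial list was higher with 0 of 8 called by limma and 1 adjusted over the list alone, KRT18 at 0.81 (camera adjusted p = 0.0432, adjusted p = 0.355 with an estimated correlation and 0.0858 with no filter). The oxidative phosphorylation list was lower with 0 of 29 called by limma or adjusted over the list alone, COX7C at -0.22 (camera adjusted p = 0.0432, adjusted p = 0.541 with an estimated correlation and 0.106 without the passage term). The mesenchymal and matrix list was called as lower only with no filter (camera adjusted p = 0.0268, against 0.0781). Without the passage term 34 genes were called, 25 in a fit of these 10 arrays alone and 1131 with array weights, and without passage 1, 5, 10, 20 or 40 the counts were 43, 58, 93, 147 and 1423. DEPTOR, TMEM158, PODXL, DOCK2, FAM50B, PAPPA and PLTP stayed called with any 1 passage left out, L1CAM lost the call without passage 1, and quantile normalization changed the split to 151 higher and 167 lower and median centring to 152 and 183.

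Of the 1006 genes that doxycycline raised in mutant cells, 113 were still called higher after withdrawal than in never-induced cells, where independent lists would share 14.3, and 110 were called lower than in cells kept on doxycycline (14.8 for independent lists). Of the 1316 it lowered, 213 were still called lower (35.0 for independent lists) and 88 were called higher than on doxycycline (14.8). The median change of the raised genes was 0.47 on doxycycline and 0.22 after withdrawal, and that of the lowered genes -0.37 and -0.20. These calls and changes are averages over the passages. The shared never-induced arrays raise the overlaps with withdrawn cells, and the shared treated arrays raise those of reversed genes. Across 8381 genes, which are not independent replicates, the 2 changes had r = 0.809, inside the range of -0.0274 to 0.876 (mean 0.493) in 100 simulations of unchanged groups that share arrays. Their covariance of 0.0775 lay above the simulated highest of 0.0333. With separate never-induced arrays for each change the median r over 20 splits was 0.683. The doxycycline effect and the change from treated to withdrawn cells had r = -0.819, inside the simulated range of -0.844 to -0.101 (mean -0.473), with a covariance of -0.0803 against a simulated lowest of -0.0288.

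From passage 1 to 20 the retained share of the doxycycline signature was lower at each later passage sampled. It compares the size of the signature in withdrawn cells with that in treated cells at the same passage, over 829 to 2046 genes called without that passage. It was 95.3% at passage 1, 69.5% at passage 5, 58.4% at passage 10, 35.7% at passage 20 and -25.8% at passage 40, with 1 array per group at each passage and no test. The slope of treated cells on the signature was 0.757, 0.777, 1.07, 1.13 and 0.712 at these passages, and that of withdrawn cells 0.722, 0.540, 0.624, 0.404 and -0.184. The background, which was not subtracted, was 0.104, 0.0783, 0.157, 0.190 and -0.389 in withdrawn parental cells. In treated ones it was 0.0939 to 0.159 at passages 1 to 20 and -0.142 at passage 40. At passage 40, another array run, the withdrawn parental slope was lower than the withdrawn mutant one, and the share became 7.74% with the mean of the 5 never-induced arrays as the baseline, so it is not read as a loss of the signature.

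**Figure D2:**
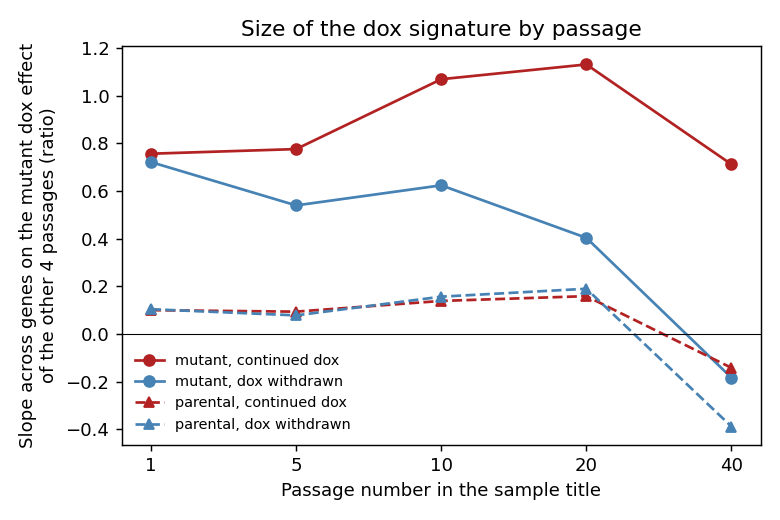
Slope across genes on the mutant doxycycline effect of the other 4 passages (vertical axis, a ratio) against the passage number in the sample title (horizontal axis), for treated and withdrawn cells of both lines, 1 value per passage. The withdrawn mutant line goes from 0.722 at passage 1 to -0.184 at passage 40, while the treated mutant line lies between 0.712 and 1.13.

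Gene by gene, no trend with passage passed the test. The difference of L1CAM between withdrawn and never-induced mutant cells had a slope of -0.54 per doubling of the passage number (SE 0.16, adjusted p = 0.213; -0.40 without passage 40), and that of CD24 one of -0.28 (SE 0.15, adjusted p = 0.48; -0.15 without passage 40). The doxycycline effect on L1CAM had a slope of -0.66 (SE 0.16, adjusted p = 0.495; -0.34 without passage 40) and that on CD24 one of 0.01 (SE 0.15, adjusted p = 0.996). IDH1 had slopes of 0.05 and 0.03 (SE 0.06) for these effects. With limma, 0 genes were called for the withdrawn effect in mutant cells and 0 for the doxycycline effect, with 972 and 419 genes at an unadjusted p under 0.05, and again 0 and 0 without the passage term, with 545 and 211. The parental line gave 0 called genes for the same trends, with 704 and 365 genes at an unadjusted p under 0.05. CD24 had parental slopes of 0.52 (SE 0.15, adjusted p = 0.531) for the withdrawn and 0.45 (SE 0.15, adjusted p = 0.989) for the doxycycline effect. Its withdrawn difference was 4.01 at passage 40 against 0.41 to 1.43 before. Parental slopes were 0.02 and -0.08 for L1CAM (SE 0.16) and -0.03 and 0.03 for IDH1 (SE 0.06). For the withdrawn effect in mutant cells 3 genes were called with a trended robust prior and 1 without passage 40.

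Parental cells taken off doxycycline again gave MSRA as the only called gene, at 8.34 ± 0.10 log2 against 7.89 ± 0.11 in never-treated cells (SD, n = 5; change 0.45, SE 0.08, adjusted p = 0.0487, higher at 5 of 5 passages). CD24 had a change of 1.48 (SE 0.36, adjusted p = 0.185, higher at 5 of 5 passages; 0.84 without passage 40), L1CAM one of -0.19 (SE 0.39, adjusted p = 0.956) and IDH1 one of -0.01 (SE 0.11, adjusted p = 0.99). The comparison is the control for withdrawal, and with limma 612 genes had an unadjusted p under 0.05. The cholesterol list was lower with 0 of 17 called by limma or adjusted over the list alone, INSIG1 at -0.40 (camera adjusted p = 1.86e-06, adjusted p = 0.545 with an estimated correlation). The NF-kB list was lower with 0 of 17 called by limma and 1 adjusted over the list alone, TNFAIP6 at -1.05 (camera adjusted p = 0.0254, adjusted p = 0.545 with an estimated correlation and 0.0998 without the passage term). MSRA was not called without the passage term, with median centring, with no filter or without passage 1, 5, 10 or 20, and 24 genes were called without passage 40 and 76 with array weights.

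The withdrawn effect differed between the lines for DEPTOR, by 2.22 (SE 0.35), with 4.32 ± 0.68 and 5.81 ± 0.52 log2 in never-induced and withdrawn mutant cells and 5.64 ± 0.62 and 4.91 ± 0.87 in parental cells (SD, n = 5). DOCK2 differed by -1.94 (SE 0.31), CNN1, the smooth muscle calponin, by -1.53, RBP4, the retinol carrier, by -1.53, and DNMT3A, a DNA methyltransferase, by -0.92. Other positive differences were AKR1B10, an aldo-keto reductase (1.31), GPRC5A (1.09), TMOD3, a tropomodulin (0.69), and PIR (0.68). Other negative ones were PLTP (-1.24), FAM50B (-1.15), LSR (-1.11), GAS1 (-1.05), COL4A5, a chain of type IV collagen (-1.05), and SCAI (-0.98). With limma, 20 genes differed, 5 more positive and 15 more negative, with 1184 at an unadjusted p under 0.05. Means under the filter value make the differences of DEPTOR, DOCK2, RBP4 and FAM50B lower bounds. Standard errors of the 15 named differences ran from 0.13 to 0.35, adjusted p from 0.0104 to 0.0474, and each had 1 sign at 5 of 5 passages. L1CAM had a difference of 2.35 (SE 0.55, adjusted p = 0.0687), and 2.91 without passage 40 (adjusted p = 0.00306), while its second probe set gave 0.58. CD24 had a difference of -0.67 (SE 0.50, adjusted p = 0.589), and 0.23 without passage 40, and IDH1 one of -0.02 (SE 0.15, adjusted p = 0.969).

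For this difference, camera called 4 lists with 0 members called by limma. The epithelial list was more positive in mutant cells, KRT18 at 1.25, with 1 member adjusted over the list alone (camera adjusted p = 0.0241, adjusted p = 0.411 with an estimated correlation and 0.224 with no filter). The cholesterol list was more positive, INSIG1 at 0.39, with 0 adjusted over the list alone (camera adjusted p = 0.0183, adjusted p = 0.646 with an estimated correlation). The oxidative phosphorylation list was more negative, COX4I1 at -0.28, with 0 adjusted over the list alone (camera adjusted p = 0.0241, adjusted p = 0.569 with an estimated correlation and 0.0634 without the passage term). The p53 list was more negative, ZMAT3 at -0.59, with 4 adjusted over the list alone (camera adjusted p = 0.0241, adjusted p = 0.529 with an estimated correlation and 0.0634 without the passage term). The count was 0 without the passage term, 3 in a fit of the 4 groups alone, 8 with passage as a random block, 13 with the stricter filter, 267 with array weights, and 0, 0, 4, 1 and 188 without passage 1, 5, 10, 20 and 40. Quantile normalization changed the split to 9 higher and 15 lower and median centring to 8 and 14.

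Without doxycycline, the mutant line had higher PRKAR2B and lower PLAC8 and POSTN than the parental line. PRKAR2B, a regulatory subunit of protein kinase A, was higher by 2.81 (SE 0.48), ADGRL2, a latrophilin, by 2.55 (SE 0.52), and PDLIM3, a protein of the actin cytoskeleton, by 2.37 (SE 0.29). PLAC8 was lower, with a change of -2.45 (SE 0.42), as was POSTN, the matrix protein periostin (-2.08, SE 0.36), on 1 of its 2 probe sets. The comparison gives the difference of the 2 lines before induction. With limma, 1192 genes differed, 683 higher and 509 lower, of which 37 and 32 changed at least 2-fold.

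Higher in the never-induced mutant line were also MFAP3L (2.35), KCNJ8 (2.20), TRHDE, a peptidase of thyrotropin-releasing hormone (2.17), MYRIP (2.08), SLITRK5 (2.02), the calcium-binding protein GCA (1.95) and TSPAN13 (1.86). Lower were ACKR3 (-1.62), MAB21L2 (-1.51), the gelatinase MMP2 (-1.43), NDRG1 (-1.42), LIMCH1 (-1.36), NUPR1 (-1.33), DEPTOR (-1.32) and DNAJC15 (-1.29). Means under the filter value hold for DEPTOR in the mutant line and, in the parental line, for PRKAR2B, ADGRL2, MFAP3L, KCNJ8, TRHDE, MYRIP, SLITRK5, GCA and TSPAN13. Standard errors of the 20 named changes ran from 0.25 to 0.52, and each had 1 sign at 5 of 5 passages. CD24 had a change of 0.71 (SE 0.36, adjusted p = 0.194; 0.33 without passage 40), L1CAM one of -0.18 (SE 0.39, adjusted p = 0.814) and IDH1 one of -0.09 (SE 0.11, adjusted p = 0.629). Mesenchymal and matrix genes were lower in 8 of 28, 11 adjusted over the list alone, COL1A2 at -1.17 and THBS1 at -0.53 (camera adjusted p = 4.94e-05, adjusted p = 0.34 with an estimated correlation). Class I genes were lower in 7 of 14, 10 adjusted over the list alone, HLA-B at -0.72 and TAP1 at -0.44 (camera adjusted p = 1.15e-06, adjusted p = 0.34 with an estimated correlation). Hypoxia genes were lower in 4 of 24, 5 adjusted over the list alone, P4HA2 at -0.58 (camera adjusted p = 0.0112, adjusted p = 0.489 with an estimated correlation). The interferon list was lower, with IFI35 at -0.34 and HERC5 at 0.65 called among 21, also adjusted over the list alone (camera adjusted p = 0.00464, adjusted p = 0.539 with an estimated correlation). Cell cycle genes were higher in 4 and lower in 1 of 30, also adjusted over the list alone, CDK1 at 0.41 (camera adjusted p = 0.018, adjusted p = 0.539 with an estimated correlation). The epithelial list was lower with 0 of 8 called by limma or adjusted over the list alone, KRT18 at -0.57 (camera adjusted p = 0.0432, adjusted p = 0.34 with an estimated correlation and 0.174 with no filter). Without the passage term 315 genes were called, with array weights 2313, and without passage 1, 5, 10, 20 or 40 the counts were 473, 511, 433, 412 and 1920. MMP2, SLITRK5, DNAJC15 and MAB21L2 lost the call without at least 1 of passages 1, 5, 10 or 20, and NUPR1 and DEPTOR without the passage term.

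In the sorted cells, CD24 was 11.5-fold higher in the positive population, at 11.47 ± 0.09 against 7.94 ± 0.08 log2 (SD, n = 2), and L1CAM was higher, at 8.31 ± 0.08 against 4.83 ± 0.11. TRIM58 had a change of 4.42 (SE 0.48), AGTR1, the angiotensin receptor, 3.91 (SE 0.18), PDZRN3, a ubiquitin ligase, 3.89 (SE 0.12), and the sodium channel SCN3A 3.72 (SE 0.11). CFI, the complement factor I protease, was lower (-2.74, SE 0.21), as were IQGAP2 (-2.71, SE 0.25) and the chemokine CCL11 (-2.64, SE 0.19). The comparison describes the CD24-positive part of doxycycline-treated mutant cells. With limma, 3035 of 8168 genes differed, 1386 higher and 1649 lower, of which 238 and 272 changed at least 2-fold. The labels do not say whether the 2 arrays of a population come from separate sorts. The p-values, and the gene sets taken from them, may therefore rest on repeats of 1 sort. RNA quality differed as well, with a mean ACTB 3' minus 5' difference of 1.59 in positive and 1.90 in negative arrays, against 1.01 in the time-course arrays of passages 1 to 20.

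Also higher in CD24-positive cells were ALDH1A3, a retinaldehyde dehydrogenase (3.50), DPYSL4 (3.48), the neuronal pentraxin NPTX2 (3.44) and SYCP2, a protein of the synaptonemal complex (3.32). Lower were PDGFRA, a receptor of platelet-derived growth factor (-2.62, 2 of 3 probe sets), the laminin chain LAMA4 (-2.50), MAB21L2 (-2.45), the cholesterol exporter ABCG1 (-2.39), SNED1 (-2.38), SCG2, a secretogranin (-2.36), and the collagen chain COL15A1 (-2.34). Standard errors of these 11 changes ran from 0.08 to 0.22. Of the 20 called named genes 14 had a mean under the filter value in 1 population, all but CD24, ALDH1A3, PDGFRA, LAMA4, MAB21L2 and SCG2. CD24 changed by 3.53 (SE 0.09) and L1CAM by 3.49 (SE 0.10), but by 0.36 on its second probe set, and IDH1 had a change of 0.06 (SE 0.07, adjusted p = 0.588). Interferon genes were lower in 18 of 26, and in 19 with 1 higher adjusted over the list alone, IFI44L at -1.71, IFITM1 at -1.53, OAS1 at -1.28 and IFIT1 at -1.27 (camera adjusted p = 3.26e-06, adjusted p = 0.641 with an estimated correlation). Histone genes were lower in 8 of 9, and in 9 adjusted over the list alone, H1-2 at -1.47 and H2AC6 at -1.42 (camera adjusted p = 4.61e-05, adjusted p = 0.338 with an estimated correlation). Class I genes were lower in 9 and higher in 1 of 14, 10 and 1 adjusted over the list alone, HLA-G at -1.46 and HLA-C at -1.22 (camera adjusted p = 0.00103, adjusted p = 0.338 with an estimated correlation). Cholesterol biosynthesis genes were higher in 13 of 16, also adjusted over the list alone, EBP at 1.09, ACAT2 at 0.98, HMGCS1 at 0.92 and IDI1 at 0.87 (camera adjusted p = 3.26e-06, adjusted p = 0.338 with an estimated correlation). Cell cycle genes were higher in 17 and lower in 3 of 30, 18 and 3 adjusted over the list alone, AURKA at 0.85, MKI67 at 0.80 and TOP2A at 0.66 (camera adjusted p = 0.00409, adjusted p = 0.338 with an estimated correlation). With 2 arrays per population the residual degrees of freedom were 2, and leaving out positive array 1 or 2 gave 1659 or 1988 genes. A fit of all 34 arrays called 1019, 528 higher and 491 lower, and ended the calls of IQGAP2, CCL11 and COL15A1.

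Genes of the CD24-positive population were lower in doxycycline-treated than in never-induced mutant cells, although CD24 and L1CAM themselves were higher. Of 1371 genes higher in positive cells, 570 fell and 57 rose (median -0.23), and of 1618 genes lower in positive cells, 574 rose and 49 fell (median 0.23). The question is whether the sorted populations' genes moved with induction and withdrawal. Camera called both sets, and both held with an estimated correlation (adjusted p = 0.0309). In parental cells the medians were -0.04 and 0.03. Camera called both sets there too, in the same directions (adjusted p = 0.00381), but they did not hold with an estimated correlation (adjusted p = 0.505). In the difference between the lines the medians were -0.20 and 0.20 (adjusted p = 0.0716 with an estimated correlation). Between withdrawn and treated mutant cells the medians were 0.12 and -0.13 (adjusted p = 0.0682 with an estimated correlation), and between withdrawn and never-induced ones -0.12 and 0.09 (adjusted p = 0.106 with an estimated correlation). For the difference of withdrawn effects they were -0.12 and 0.09 (adjusted p = 0.231 with an estimated correlation). Withdrawn parental cells gave medians of -0.00751 and -0.000826 (camera adjusted p = 0.681 and 0.986). Between the lines without doxycycline, the higher set had 352 genes higher and 14 lower, and both sets held with an estimated correlation (adjusted p = 0.0132).

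Across 8062 genes, which are not independent replicates, the sort change correlated with the doxycycline effect in mutant cells at r = -0.454 (Spearman -0.520) and in parental cells at r = -0.116. For withdrawn against treated mutant cells r was 0.428, and for the lines without doxycycline 0.593. These 2 comparisons share mutant arrays with the doxycycline effect, and an opposite sign tends to follow from that alone. Between the doxycycline effect and these comparisons r was -0.819 and -0.506, against means of -0.473 and -0.483 in simulations of unchanged groups (ranges -0.844 to -0.101 and -0.852 to 0.0997), so their r with the sort change is no separate evidence. The covariances of -0.0803 and -0.0581 lay below the simulated lowest of -0.0288 and -0.0282. With separate arrays for each comparison the median r over 20 splits was -0.671 and -0.420. Array-to-array variation of the shared arrays therefore does not give all of the opposition between these effects. A departure of a shared culture as a whole would lie in all of its arrays, so neither check can exclude it. A CD24 sort index, the mean of the higher set minus that of the lower set, was 0.748 ± 0.230 in never-induced mutant arrays, 0.217 ± 0.156 in treated ones and 0.520 ± 0.213 in withdrawn ones (SD, n = 5). It was 0.279 ± 0.166, 0.215 ± 0.0905 and 0.286 ± 0.198 in the same groups of the parental line. Without passage 40, the other array run, the means were 0.840, 0.266 and 0.441 in the mutant and 0.347, 0.205 and 0.205 in the parental line. At passages 1 to 20 the parental index was lower than in never-treated cells in 4 of 4 treated and 4 of 4 withdrawn arrays, with mean differences of -0.141 and -0.142. At passage 40 it was higher in withdrawn than in never-induced mutant cells (0.837 against 0.376), and in withdrawn (0.610) and treated (0.253) than in never-treated parental cells (0.00977). The sorted arrays, from which the index was built, had -0.585 in negative and 0.825 in positive cells.

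**Figure D3:**
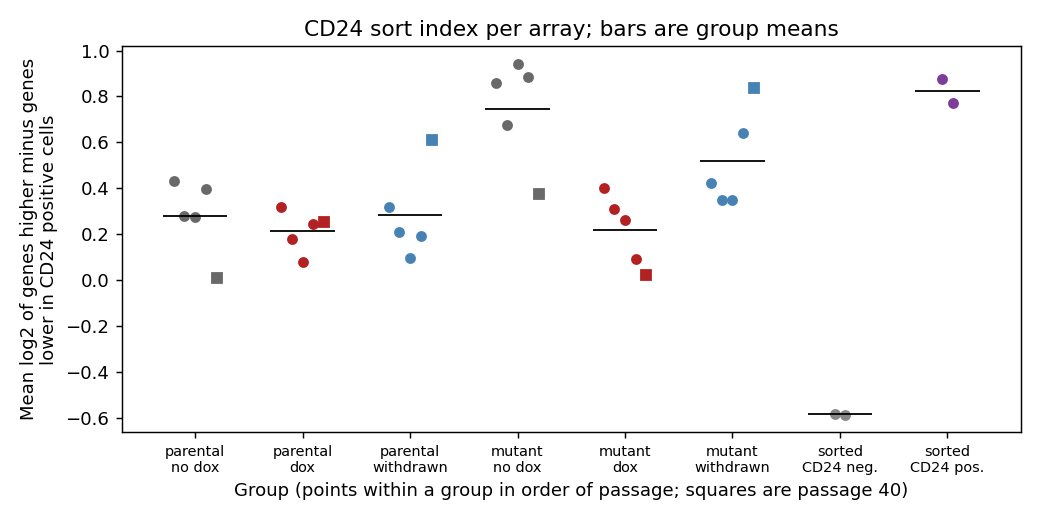
CD24 sort index per array (vertical axis, log2) for the 8 groups (horizontal axis), with points in order of passage, squares for passage 40 and bars for group means. The never-induced mutant mean of 0.748 lies above the treated mean of 0.217 and the withdrawn mean of 0.520.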

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

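The tests chosen after the result was seen are those of exchanged sort labels, of a larger share of CD24-positive cells, of doxycycline alone, for the set and for CD24, and of RNA quality in treated arrays for the first pattern, and that of the array run for the third, and the limit on how much the RNA quality test of the sorted arrays must remove was also set then.

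Genes higher in CD24-positive cells fell as a set in doxycycline-treated mutant cells, while CD24 and L1CAM rose, and exchanged labels of the sorted populations are argued against by CD24 itself, higher by 3.53 (SE 0.09) in the arrays called positive. A larger share of CD24-positive cells alone would raise the set, whose median change was -0.233 on average over the passages (SE 0.0320). This fall is the pattern itself and so no separate test. A larger share beside another change of these genes stays open as a source of the CD24 and L1CAM rises. Doxycycline alone, as the whole source, is argued against for the set by r = -0.407 across genes, which are not independent replicates, with the difference between lines. The set median was also lower than in parental cells at 5 of 5 passages (mean -0.197, SE 0.0506; camera adjusted p = 0.0716 with an estimated correlation). A part from doxycycline stays open, because camera called the set lower in parental cells too (adjusted p = 0.00381; 0.505 with an estimated correlation). Doxycycline alone also stays open for CD24, whose parental change was 1.20 without a call. The difference of CD24 between lines was 0.47 (SE 0.50, adjusted p = 0.602; 0.97 without passage 40, adjusted p = 0.0323). The ACTB 3' minus 5' difference was higher in treated mutant arrays at 5 of 5 passages, but as the whole source of the fall it is argued against by the CD24 sort index, which changed by -0.161 (SE 0.218) per unit of it within groups and passages, where -3.81 would be needed (GAPDH -1.40, SE 0.918, against -8.42). RNA quality of the sorted arrays and a change within the cells cannot be told apart, because r was -0.450 after its predicted part was removed and -0.454 before, but that part had an SD of 0.0774 against 0.541 for the sort change and was predicted from arrays with ACTB differences up to 1.42, under the 1.54 or more of the sorted arrays. A departure of the never-induced mutant culture also stays open and was not tested. Its mean sort index was 0.748, against 0.217 in treated and 0.520 in withdrawn mutant arrays. In never-treated, treated and withdrawn parental arrays the index was 0.279, 0.215 and 0.286.

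Doxycycline-treated and withdrawn parental cells departed from never-treated parental cells in the same direction across genes, with r = 0.768 against a mean of 0.462 and a highest value of 0.781 in 100 simulations of unchanged groups with shared arrays. The shared never-treated arrays could therefore give this value. With separate never-treated arrays for each comparison the covariance stayed above 0 in all 20 splits, at a lowest of 0.0105, so a departure of the never-treated culture, or a change shared by the other cultures, could also give it. Both stay open, and no biological explanation was tested.

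L1CAM was low at passage 40 in doxycycline-treated mutant cells, at 5.10 against 5.59 in never-induced cells. The array run of passage 40 stays open, because L1CAM differed from passages 1 to 20 by -0.16 on average in the other 5 groups (SE 0.37), but 4 of these had too little L1CAM to fall, and withdrawn mutant cells differed by -1.39. An exchange of the treated and never-induced arrays, and a loss of the whole doxycycline effect, are both argued against by the signature's slope of 0.712 at that passage, where an exchange would give a slope below 0 and a loss one below 0.5. The margin over 0.5 is just above the SD of 0.196 between passages. A change of L1CAM in that culture late in passage stays open and untested.

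Among 140 sets of 5 values per passage, 7 held a value far from the other 4, each at passage 40, the other array run. The share of 5% is what chance gives, while chance would spread the 7 over the passages. For the difference of doxycycline effects between lines, L1CAM was at -0.60 against 2.36 to 3.20, and RAB38 at -4.93 against -1.98 to -0.96. FBXO2 was at -4.86 for withdrawn against continued doxycycline (others -1.50 to -0.62), TNFRSF21 at 0.20 for withdrawn against never-induced mutant cells (1.32 to 1.48), and CD24 at 4.01 for the same comparison in parental cells (0.41 to 1.43). AKR1B10 was at 2.59 for the difference of withdrawn effects (0.73 to 1.16) and TRHDE at 1.09 between the lines without doxycycline (2.22 to 2.56).

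The effects of the 2 lines differed by the test of the difference itself. For doxycycline 795 genes differed, among them COLEC12 (4.59), CAPN6 (4.31), DEPTOR (3.35), AKR1C3 (3.11), ADGRG6 (3.07), SERPINB3 (2.95), ACTC1 (2.56), LIMCH1 (2.50), HS3ST3A1 (2.36), CXADR (2.33) and L1CAM (2.24). Negative differences were those of MEOX2 (-3.79), COL3A1 (-3.58), KCNJ8 (-3.06), NLGN1 (-2.78), THBS2 (-2.38), RAB38 (-2.32), VCAM1 (-2.29), LGR5 (-2.22), KCNE4 (-2.21) and RCAN2 (-2.20). For withdrawal 20 genes differed, among them DEPTOR (2.22), AKR1B10 (1.31), GPRC5A (1.09), TMOD3 (0.69), PIR (0.68), DOCK2 (-1.94), CNN1 (-1.53), RBP4 (-1.53), PLTP (-1.24), FAM50B (-1.15), LSR (-1.11), GAS1 (-1.05), COL4A5 (-1.05), SCAI (-0.98) and DNMT3A (-0.92). Among 1557 probe sets without exactly 1 gene symbol, left out of the comparisons, 287 were called for doxycycline in mutant cells, 113 higher and 174 lower, and 0 in parental cells with limma.

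Chance as the source of the counts was tested on 100 splits of the same arrays, the real one included. For the doxycycline effect in mutant cells 1 split, the real one, reached 2322 genes, and the highest other gave 1312, with treated passage 5 and never-induced passage 40 exchanged. The real split alone (1 of 100) was also the highest for the difference of doxycycline effects (795, highest other 6), withdrawn against continued doxycycline (217, highest other 75), the difference of withdrawn effects (20, highest other 3) and the lines without doxycycline (1192, highest other 549). For withdrawn against never-induced mutant cells 2 splits reached 342, the other with 580 genes when the passage 40 arrays, the other array run, were exchanged, and without passage 40 the count was 1423. The single gene of the parental doxycycline effect was reached by 2 splits (highest other 1) and that of the parental withdrawn effect by 4 (highest other 4), under 5 of 100 each. For the trends the real counts of 0 were reached by 100 of 100 splits, as a count of 0 always is, so the test says nothing there. The split with 1043 genes exchanged treated and never-induced mutant arrays at passages 10, 20 and 40. That with 129 exchanged withdrawn and never-induced ones at passages 10 and 20, where passage 40 already had a signature slope of -0.184. Such an exchange by itself turns a steady difference into a trend, so these counts show no further structure of the samples. Among the 16 splits that part every pair of a passage, the highest others were 421, 0, 54, 75, 580, 4, 165 and 3 for these 8 comparisons in the report's order with the lines last. These splits are too few for a share under 0.05. The 580 and the 4, each with passage 40 exchanged, and the 165 exceeded the real 342, 1 and 20, so chance is not excluded for these 3 counts. For differences of effects only the mutant arrays were exchanged, for the 165 those of passages 1, 5, 10 and 20. Changes shared by both lines then enter the count, so these splits cannot decide on chance there. For the other 5 the share is under 0.05 only in the 100 splits, which also exchange arrays between passages, and 1 of the 5 is the single parental gene MSRA, lost without the passage term or any of passages 1, 5, 10 or 20.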

How the results depend on the processing

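All alternatives below were chosen before the data were examined, and no test in this part was added after a result was seen. Of 2353 values of named genes under the alternatives, 2032 kept their direction and side of the threshold, 292 were no longer called, 7 became called and 22 changed sign. Signal over background limits genes near the filter of 4.83 log2. Causes were not tested except where a setting leaves fewer arrays or tests more or fewer genes.

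Counts without the passage term were 1187 for the mutant doxycycline effect (2322), 0 for the parental one (1), 220 for their difference (795), 36 for withdrawn against continued doxycycline (217), 34 for withdrawn against never-induced mutant cells (342), 0 in parental cells (1), 0 for the difference of withdrawn effects (20) and 315 between the lines (1192). Leaving out 1 passage gave, in the same order, 1426 to 2874, 0 to 7, 265 to 1140, 7 to 324, 43 to 1423, 0 to 24, 0 to 188 and 412 to 1920, and 0 to 1 for the withdrawn trend. With array weights the counts were 24 for the parental doxycycline effect, 1484, 100, 1131, 76, 267 and 2313 from the difference onward. In fits of the compared groups alone, which have fewer arrays, they were 0 (parental doxycycline), 0 (withdrawn against continued), 25 (withdrawn against never-induced), 0 (parental withdrawn) and 3 (difference of withdrawn effects). No filter gave 2 (parental doxycycline) and 115 (withdrawn against continued), and the 60th percentile 4 (parental withdrawn) and 13 (difference of withdrawn effects). The trended robust prior gave 2, 3 and 3 for the parental doxycycline and withdrawn effects and the withdrawn trend. For the parental withdrawn effect quantile normalization gave 5, median centring 0 and a random block 2, and a random block gave 8 for the difference of withdrawn effects. The sort gave 1019 with all 34 arrays in one fit and 1659 to 2471 without 1 array, where a lone array is assumed to vary like the others.

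Lists called with an estimated correlation were 0 in every comparison. With fry they were 9 (mutant doxycycline, 4), 0 (parental, 3), 2 (difference, 4), 1 (withdrawn against never-induced, 5), 0 (parental withdrawn, 2), 0 (difference of withdrawn effects, 4) and 10 (sort, 5), and without the passage term 3, 1 and 2 for withdrawn against never-induced, parental withdrawn and the difference of withdrawn effects. Lists called with fry but not with camera were the astrocyte (adjusted p = 0.000149), neuron (0.000470), mesenchymal (0.00452), NF-kB (0.0255) and G-CIMP (0.00314) lists for mutant doxycycline, astrocyte for withdrawn against continued (0.0310), G-CIMP between the lines (0.0263) and, for the sort, neural progenitor (0.0150), astrocyte (0.00212), mesenchymal (0.0177), epithelial (0.0150) and G-CIMP (0.0290). For the 2 CD24 sort sets, adjusted p with an estimated correlation was 0.505 for parental doxycycline, 0.0716 for the difference, 0.0682 for withdrawn against continued, 0.106 for withdrawn against never-induced and 0.231 for the difference of withdrawn effects. With fry it was 0.614 (parental doxycycline), 0.133 (withdrawn against never-induced, lower set), and 0.190 and 0.313 (difference of withdrawn effects). For the lower set in withdrawn parental cells the direction changed with fry (limma adjusted p = 0.925) and with no filter (0.826).

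Signs changed only for values that were not called, most of them near 0, apart from CD24 for the difference of withdrawn effects. L1CAM for withdrawn against continued doxycycline was 0.042 with the mean of probe sets and 0.020 with quantile normalization, and L1CAM for parental doxycycline 0.036 with array weights. IDH1 was 0.011 with median centring for the difference of withdrawn effects and 0.017 with array weights for the parental withdrawn effect. Leaving out 1 passage, L1CAM ran from -0.23 to 0.14 for withdrawn against continued doxycycline, from -0.18 to 0.11 for parental doxycycline and from -0.41 to 0.051 between the lines. IDH1 ran from -0.0096 to 0.080 for parental doxycycline, from -0.10 to 0.062 for withdrawn against never-induced mutant cells, from -0.051 to 0.026 for the parental withdrawn effect, from -0.11 to 0.084 for the difference of withdrawn effects and from -0.033 to 0.099 for the withdrawn trend. CD24 ran from -1.03 to 0.23, against -0.67 with all passages, for the difference of withdrawn effects and from -0.16 to 0.043 for the doxycycline trend. The retained share at passage 40 was 7.74% with the mean of all 5 never-induced arrays as the baseline, and at passages 1, 5, 10 and 20 the alternatives gave 93.9% to 98.9%, 67.0% to 75.1%, 55.5% to 64.0% and 31.6% to 36.4%.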

Other observations

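The lists and tests in this part were fixed before the data were examined, and none was chosen after a result was seen.

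Several lists that camera did not call between the sorted populations held members that moved apart. Of 18 NF-kB genes 8 were higher in CD24-positive cells and 8 lower, also adjusted over the list alone, with the cytokine IL6 at 2.07, TNFAIP3 at 1.41 and the chemokine CXCL2 at -1.47 (limma; camera adjusted p = 0.891). Of 28 mesenchymal and matrix genes 6 were higher and 11 lower, 6 and 12 adjusted over the list alone, with COL6A3 at 2.42 and the proteoglycan DCN at 1.79 against the type I collagen chains COL1A2 at -2.04 and COL1A1 at -1.59 (camera adjusted p = 0.233). Of 9 astrocyte genes 2 were higher and 4 lower, also adjusted over the list alone, with AGT at -2.07, the glutamate transporter SLC1A3 at -1.32, CLU at -0.71 and GLUL at -0.63 (camera adjusted p = 0.509, median 0.00671 and mean -0.283). Of 14 neural progenitor genes 4 were higher and 4 lower, also adjusted over the list alone, with NES, the intermediate filament nestin, at -1.92 and PAX6 at 0.89 beside CD24 and L1CAM (camera adjusted p = 0.63). Of 23 chromatin enzymes 5 were higher and 3 lower, also adjusted over the list alone, with DNMT3B at 1.48, KDM5A at 0.51, EZH2 at 0.40 and EZH1 at 0.38 (camera adjusted p = 0.841, median -0.0134 and mean 0.0538). The ACTB 3' minus 5' difference of 1.59 in positive and 1.90 in negative arrays holds for these genes too.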
